A study of Mus musculus with 12 samples.

How the data were processed

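The data are 12 RNA-seq libraries of primary mouse aortic smooth muscle cells, 6 from C57BL/6J mice and 6 from CSE knockout mice, each grouped by the genotype in its label, and all treated with angiotensin II at 1 uM for 24 h. Per the labels' protocols, polyadenylated RNA was purified and fragmented, and strand was marked with dUTP before paired-end sequencing; whether strand was used in counting is not given in the sources used here, so values of overlapping and antisense genes are uncertain. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2, edgeR and the build mm9, without saying what each was used for.

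The deposited values are FPKM, fragments scaled by gene model length and by the mapped fragments of the library, made by the authors and given to 2 decimals for 29462 genes, of which 402 are at 0 in all libraries. The same deposited table holds the authors' own comparison: a ratio of the mean FPKM of WT over that of KO, its log2, a p-value and a q-value, and a mark for significant genes. The test behind the p-value is not given in the sources used here; genes marked significant have an absolute log2 ratio of at least 1 and a q-value of at most 0.05. By its construction FPKM is relative to the other genes of a library, so a gene family that takes a larger share lowers the values of the rest, and reads shared by near-identical genes can be split between them in an unknown way. Depth in reads is unknown, because no counts were used here and the FPKM are estimates that do not fall on whole multiples of 1 read. The most frequent value above 0.05 FPKM among genes of microRNAs and other short RNAs, which scales with what 1 read is worth, was 0.16 to 0.18 in all 12 libraries. A value of 0 in the file is reported as listed at 0.

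Gene IDs were matched to GENCODE M21, the annotation of the mouse build GRCm38, and 29384 of 29462 matched. The table has no coordinates, and all positions given are those of GRCm38, not of the build named in the processing notes. 56 symbols stand on more than 1 row; for a listed symbol the row with the highest mean was used. No column belonged to a sample outside the series, and no 2 libraries held the same values: at most 3.37% of tested genes lay within 0.01 FPKM of each other in any pair.

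Genes with at least 1 FPKM in at least 6 of the 12 libraries were tested, 11831 in all. log2(FPKM + 1) was compared between genotypes with limma 3.58.1 in R 4.3.3, with a trend of variance on mean level and no covariate, and p-values were adjusted by Benjamini-Hochberg over all genes tested, two-sided, at 0.05. A fold change on this scale understates the change of low genes; folds given as such are ratios of mean FPKM. Genes below the threshold for testing were compared by an exact permutation test over all 924 assignments of the libraries. Lists of genes were compared with camera of limma with a preset correlation of 0.01 between genes and, as an alternative, with a correlation estimated for each list, adjusted over the 27 of 30 lists with at least 3 tested genes. For each list, calls were also counted with p-values adjusted over the list alone. With an estimated correlation none of the 27 passed, and 1 had an unadjusted p under 0.05. With the preset correlation, 33 of 100 splits of the 12 libraries into groups of 6 called at least the real 8 lists. List calls given below therefore describe these libraries and do not exclude chance.

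The design, the lists and the alternatives were set before the data were examined. Named genes are Cth, the 10 largest rises and 10 largest falls on the log2 scale among called genes whose 6 KO values all lie on 1 side of the 6 WT values, with a mean of at least 2 FPKM in a genotype and a symbol that is not a predicted gene, clone or pseudogene, the 5 largest differences in mean FPKM, up to 3 called members of each list with the smallest p, and Xist with 4 Y-linked genes. Acta2, Mki67 and the other markers given per library, the genes that complete counts of 5 or fewer, and those of the closing section were chosen after their values were seen. Some genes that the rule names are not reported here.

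Alternatives covered the pseudocount, the filter on low values, median-ratio, TPM and quantile scaling, the variance model, weights per library, an exact rank-sum test, the replicate number as a block, a minimum size of change and each library left out. Added after seeing the data were KO replicates 1 to 4 only, autosomal genes only and protein coding genes only. A planned adjustment for the sex of the cells was not run, since the WT libraries lack Xist while each KO library holds both Xist and Y-linked RNA. A count test was not run because the file holds no counts.

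The tests were checked on simulated data for this comparison: the 11831 genes with their real WT means and the spread within both genotypes, and 200 genes changed by a known factor. Of 50 genes changed by 0.5 on the log2 scale of FPKM 60% were called, of 50 changed by 1, 2 or 4 it was 90%, 98% and 100%, and 6 of 11631 unchanged genes were called. A list of 47 genes shifted by 0.5 was called, also with an estimated correlation, and none of 26 unshifted lists was. The simulated noise was independent between genes, whereas the correlation estimated in the real lists reached 0.86. The check therefore does not show how often unshifted lists are called in the real data. The exact rank-sum test called 0 of the 200 changed genes. This was fixed in advance: with 6 against 6 libraries its smallest p cannot pass an adjustment over 11831 genes when so few change. It therefore does not measure the power of that test, which called 7075 genes in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.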

Results

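RNA was measured in primary smooth muscle cells from the mouse aorta, taken from C57BL/6J mice (WT) and from mice that lack cystathionine gamma-lyase in all tissues (KO). This enzyme, abbreviated CSE and encoded by Cth, makes hydrogen sulfide from cysteine. All cultures received angiotensin II, a vasoconstrictor peptide used to model aortic aneurysm, at 1 uM for 24 h, so the data hold 1 comparison, KO against WT under angiotensin II, with 6 libraries of polyadenylated RNA per genotype. No untreated cells were analysed here, and the response to angiotensin II itself cannot be read from these libraries. The labels do not say whether the 6 libraries of a genotype came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The deposited FPKM summed to between 255538 and 281432 per library, and depth in reads is unknown. Values below are mean FPKM ± SD over the 6 libraries of a genotype (n = 6 each), and adjusted p-values are from limma unless another test is named.

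The targeted gene came first, as a check of the labels. Cth, on chromosome 3 from 157894248 to 157925077 on the minus strand of GRCm38 (GENCODE M21), was close to 0 in both genotypes, at 0.0233 ± 0.0288 FPKM in WT and 0.005 ± 0.00837 in KO. The WT libraries held 0.08, 0, 0.01, 0.02, 0.02 and 0.01 FPKM, and the KO libraries 0, 0, 0, 0.01, 0.02 and 0. The difference of -0.03 on the log2(FPKM + 1) scale did not pass with all libraries (exact permutation p = 0.143, two-sided). It passed without WT replicate 2 (exact permutation p = 0.0325) and with quantile normalization and no filter on low values (p = 0.0411), and was -0.01 without WT replicate 1. At this level Cth neither bears out nor contradicts the genotype labels. The WT libraries held at most 0.08 FPKM, so the values do not establish a loss of Cth RNA in KO. Differences between the genotypes given below therefore cannot be ascribed to such a loss in these cells from these data. In the authors' deposited table its q-value was 0.21, not significant. Of the other enzymes that make hydrogen sulfide, Cbs was at 0.298 ± 0.0725 FPKM in WT and 0.245 ± 0.0281 in KO (exact permutation p = 0.0758), and Mpst at 9.84 ± 0.33 and 10.5 ± 1.58 (adjusted p = 0.47).

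KO and WT libraries differed across much of the transcriptome. Among the steepest rises in KO was that of Pdpn, the membrane glycoprotein podoplanin, from 2.16 ± 0.271 to 109.6 ± 9.41 FPKM, which is 50.7-fold (log2 change 5.13 ± 0.073 SE, adjusted p = 1.5e-14). The steepest fall was that of Sfrp2, a secreted modulator of Wnt signalling, from 55.1 ± 3.96 to 0.132 ± 0.083 FPKM, 419-fold lower (log2 change -5.63 ± 0.065 SE, adjusted p = 2.8e-15). Of 11831 genes tested, 7515 (63.5%) passed an adjusted p of 0.05, 3858 of them higher and 3657 lower in KO. With quantile normalization more were lower than higher, 4101 against 3493. On the log2(FPKM + 1) scale 6363 of the called genes moved by less than 1, while 738 were higher and 414 lower by at least that much. These counts depend on the scale: 681 and 730 were lower by at least 1 with pseudocounts of 0.1 and 0.01, and 1325 were higher and 724 lower with TPM rescaling. In 5484 genes (46.4%) the 6 KO values did not overlap the 6 WT values, where chance gives 0.216%. The authors' deposited table marked 4411 genes as significant, 2943 of them higher in KO and 1468 higher in WT; 1675 of the 4411 were tested here, and 1668 of these were called with the same direction.

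Genes with large rises included those of secreted and matrix proteins. Col3a1, a fibrillar collagen chain on chromosome 1 from 45311538 to 45349706 in GRCm38, rose from 0.593 ± 0.0948 to 106 ± 65.3 FPKM (179-fold, adjusted p = 4.2e-07), although KO replicates 5 and 6 held 19.57 and 25.31 FPKM where the others held 140.79 to 154.74. Gpx3, the secreted glutathione peroxidase, rose 176-fold to 80.8 ± 38.1 FPKM, with 34.03 and 29.72 in KO replicates 5 and 6. Serpinf1, which encodes pigment epithelium-derived factor, rose 193-fold to 43.5 ± 11.7 FPKM. Gas1, a cell surface protein that binds hedgehog ligands, was at 0.0183 ± 0.016 FPKM in WT and 36.7 ± 15.1 in KO. Nsg1, Plac8, Tnfaip2 and the kinase gene Mark1 rose 73.1-, 98-, 86.1- and 336-fold. The adjusted p of these genes and Pdpn lay between 1.5e-14 and 4.2e-07.

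Among the largest falls was Cdh1, the epithelial adhesion protein E-cadherin, which was at 65 ± 1.69 FPKM in WT and 0.86 ± 0.314 in KO (75.6-fold lower, adjusted p = 1.2e-13). The water channel gene Aqp1 fell 53.4-fold, the tetraspanin gene Tspan8 81-fold, the actin-bundling gene Fscn1 34.8-fold and Adamtsl3 51.8-fold. Igfbp3, which binds insulin-like growth factors, fell 19.7-fold from 88 ± 10.8 FPKM, and the ligand gene Wnt4 fell 20-fold from 48.8 ± 2.26. Cxcl15, a chemokine known from lung, fell from 181 ± 14.4 to 11.7 ± 7.94 FPKM and Clca3a2 from 160.4 ± 14.3 to 10.4 ± 7.07. In KO replicates 5 and 6 these 2 genes were lower still, Cxcl15 at 1.64 and 1.27 FPKM and Clca3a2 at 1.02 and 1.58. The largest differences in absolute level were in Lgals1, which rose from 860.1 ± 43.9 to 2111 ± 189.7 FPKM, and in Aldh3a1, an aldehyde dehydrogenase, which fell from 1362 ± 56.9 to 216 ± 100.3. Eef1a1, the translation elongation factor, fell 1.35-fold to 2520.1 ± 287 FPKM, and mt-Atp8 and mt-Co1 fell 1.31- and 1.18-fold (adjusted p = 0.0097 and 0.029). The call of mt-Co1 was lost without WT replicate 5 or 6 (adjusted p = 0.053 and 0.061) and with the replicate number as a block (0.066). Both calls were lost with no filter on low values (adjusted p = 0.11 for mt-Atp8 and 0.41 for mt-Co1) and with quantile normalization (0.16 for mt-Atp8). Quantile normalization gives genes of the same rank the same value, and it left no change in mt-Co1 at all. For genes this abundant, a call lost under it is weak evidence against a fall.

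**Figure D1:**
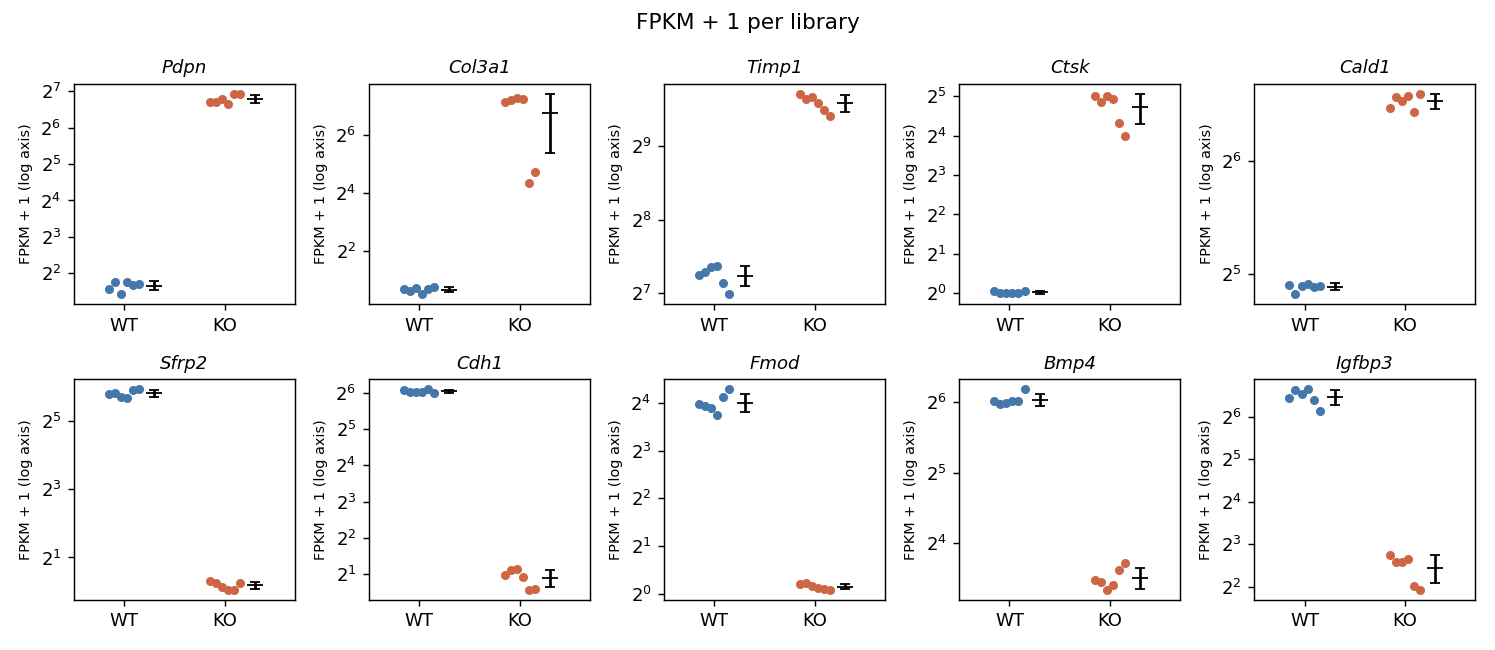
FPKM plus 1 on a log axis for 10 genes, each point 1 library of WT (blue, 6) or KO (orange, 6), with the mean and SD as black bars beside them. The top row holds genes higher in KO, such as Pdpn at 109.6 against 2.16 FPKM, and the bottom row genes lower in KO, such as Sfrp2 at 0.132 against 55.1 FPKM; in Col3a1, KO replicates 5 and 6 lie below the other KO libraries.

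Libraries of the KO genotype were less uniform than those of WT. The first principal component, with 76.8% of the variance, parted the genotypes, and the second, with 14.2%, placed KO replicates 5 and 6 at -30.42 and -35.18 against 14.87 to 18.62 for KO replicates 1 to 4. Correlations across genes were 0.992 to 0.995 between WT libraries, at least 0.993 among KO replicates 1 to 4, 0.947 to 0.96 between these and KO replicates 5 and 6, and 0.864 to 0.895 between genotypes. When KO replicates 5 and 6 were left out, a choice made after seeing the data, 9119 genes were called, 4724 higher and 4395 lower in KO, and 97.9% of the 7515 were among them.

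**Figure D2:**
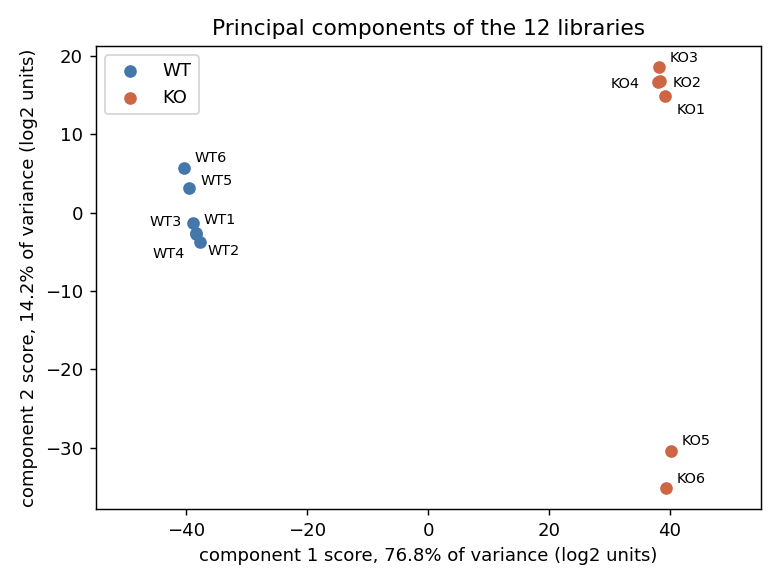
Scores of the 12 libraries on the first and second principal components of log2(FPKM + 1), in log2 units, with WT in blue and KO in orange. The WT libraries lie together on the left, KO replicates 1 to 4 at the upper right and KO replicates 5 and 6 at -30.42 and -35.18 on the second axis.

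Genes of the extracellular matrix and its turnover moved in both directions, with more rises than falls. Of 33 structural matrix and elastic fibre genes tested, 18 rose and 7 fell. Tnc, the matrix glycoprotein tenascin C, rose 8.18-fold to 72.4 ± 9.56 FPKM, whereas Fmod, a collagen-binding proteoglycan, fell from 15.1 ± 2.1 to 0.108 ± 0.0417 and Col15a1 from 3.73 ± 0.321 to 0.248 ± 0.0553. Adjusted over the list alone, 25 were called, as over all genes. The list as a whole was higher in KO (camera adjusted p = 0.041; adjusted p = 0.83 with an estimated correlation), and the call was lost without KO replicate 2, 3 or 4 (adjusted p = 0.055, 0.053 and 0.058), with a minimum of 5 FPKM (0.11) and among protein coding genes (0.072).

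Protease inhibitor genes that were called all rose in KO, and protease genes rose more often than they fell. All 10 called members of the 14 protease inhibitors tested rose, among them Serpinf1 and Timp1, the metalloproteinase inhibitor, which went from 150 ± 14.8 to 768 ± 61.2 FPKM (adjusted p = 1.5e-11). The remaining 4, Timp2, Reck, Serpinb9 and Tfpi, did not pass the test; 10 were also called adjusted over the list alone, and the list was higher in KO (camera adjusted p = 0.00026; adjusted p = 0.67 with an estimated correlation). Of 31 matrix-degrading proteases tested, 17 rose and 7 fell, with 24 called adjusted over the list alone. Mmp10, a stromelysin, rose from 0.128 ± 0.0937 to 24 ± 4.47 FPKM, Adamts4, an aggrecanase, 9.86-fold to 8.71 ± 1.73, and Ctsk, the collagen-degrading cathepsin K, from 0.0167 ± 0.0258 to 25.5 ± 6.9. The protease list did not pass the test with all libraries (camera adjusted p = 0.076) and passed it without KO replicate 5 (adjusted p = 0.028) and with KO replicates 1 to 4 only (adjusted p = 0.0047).

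Inflammatory and interferon genes were mostly higher in KO. Among 36 inflammatory cytokine and NF-kB genes tested, 22 rose and 8 fell, with 31 called adjusted over the list alone. Tnfaip2 rose from 0.572 ± 0.0838 to 49.2 ± 6.23 FPKM, Ptges, the inducible prostaglandin E synthase, from 0.0567 ± 0.0301 to 30.7 ± 7, and Csf3, a granulocyte growth factor, from 0.00833 ± 0.0204 to 2.4 ± 0.453. Of 28 interferon response genes tested, 24 rose, Ifi47 and Irgm1 fell, and 26 were called adjusted over the list alone. Oas1a, which senses double-stranded RNA, rose 22.6-fold to 6.56 ± 1.54 FPKM, the ubiquitin-like modifier Isg15 8.52-fold to 9.21 ± 2.74, and Usp18, which removes it from proteins, 14.9-fold to 2.53 ± 0.835. Camera placed the inflammatory list higher in KO at an adjusted p of 0.032 and the interferon list at 0.00013; with an estimated correlation each had an adjusted p of 0.67. Among genes at 5 FPKM or more in at least 6 libraries neither passed (adjusted p = 0.56 and 0.052), nor did the inflammatory list among protein coding genes (0.059).

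Stress response genes of the endoplasmic reticulum and of amino acid supply rose more often than they fell. In the list for the unfolded protein response, 18 of 26 tested genes rose, Herpud1 fell and 7 did not pass, with 19 called adjusted over the list alone. Creld2 rose 2.67-fold to 29.6 ± 2.23 FPKM, and the chaperone genes Calr and Hsp90b1 rose 1.6- and 1.58-fold. Of 47 ATF4 and amino acid response genes tested, 28 rose and 10 fell, with 38 called adjusted over the list alone. Atf4, the transcription factor of this response, rose from 38.3 ± 2.67 to 65.6 ± 2.58 FPKM, the threonyl-tRNA synthetase gene Tars rose 2.3-fold, and Cebpg fell 1.74-fold. Camera placed both lists higher in KO, at adjusted p-values of 0.00099 and 0.033. With an estimated correlation both had an adjusted p of 0.67. The ATF4 list lost its call with quantile normalization (adjusted p = 0.073), with KO replicates 1 to 4 only (0.054), with a minimum of 5 FPKM (0.068) and among protein coding genes (0.062).

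Genes of sulfur amino acid metabolism, the pathway of the deleted enzyme, rose more often than they fell. Of 28 tested genes for transsulfuration, the methionine cycle and sulfide metabolism, 14 rose and 5 fell, none by 1 or more on the log2(FPKM + 1) scale, which shrinks changes of low genes, and 19 were called adjusted over the list alone. Mtr, methionine synthase, rose 1.51-fold to 5.36 ± 0.386 FPKM. Ahcyl2 fell 2.28-fold to 0.93 ± 0.0651 and Kyat1, a cysteine conjugate beta-lyase, 2.5-fold to 0.98 ± 0.27; Sqor, which oxidises sulfide, Suox and Gclc were the other 3 that fell. Cdo1, a cysteine dioxygenase below the threshold for testing, was at 0.442 ± 0.135 FPKM in WT, at 5.74 to 6.62 in KO replicates 1 to 4 and at 0.96 and 0.25 in KO replicates 5 and 6. The list did not pass the camera test (adjusted p = 0.38). Of 50 NRF2 and antioxidant genes, 26 rose and 13 fell, with 41 called adjusted over the list alone. Gpx7, an endoplasmic reticulum peroxidase, was at 0.00833 ± 0.0133 FPKM in WT and 18.2 ± 2.05 in KO, and Gpx8 and Cbr1 rose 2.53- and 2.22-fold. That list did not pass with all libraries (camera adjusted p = 0.076) but passed without KO replicate 6 (adjusted p = 0.042) and with KO replicates 1 to 4 only (adjusted p = 0.028).

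TGF-beta and BMP pathway genes fell more often than they rose. Of 40 tested, 23 fell and 10 rose, with 34 called adjusted over the list alone. The ligand gene Bmp4 fell from 64.6 ± 3.57 to 10.4 ± 1.14 FPKM (6.21-fold, adjusted p = 2.7e-12), and Smad6, an inhibitor of BMP signalling, from 21.6 ± 0.947 to 5.71 ± 0.322. As a list these genes did not pass the test (camera adjusted p = 0.076).

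Most of the genes that define contractile smooth muscle were below the threshold for testing in both genotypes. Myh11, the smooth muscle myosin heavy chain, was at 0.0133 ± 0.00516 FPKM in WT and 0.00833 ± 0.0117 in KO, Tagln at 0.153 ± 0.119 and 0.695 ± 0.368, Cnn1 at 0.00833 ± 0.0133 and 0.135 ± 0.0698, and 13 of the 30 listed genes could be tested. In WT the epithelial genes Cdh1 and Krt19 were at 65 and 78.5 FPKM, while Krt8 and Krt18 of the same list were at 0.223 and 0.0467. Of the 16 epithelial and mesothelial genes listed, 6 could be tested. The cells are called smooth muscle cells after the labels, and the values of Myh11, Tagln and Cnn1 do not bear out that identity. The epithelial genes do not go one way and do not settle another identity. Cald1, caldesmon, rose 3.18-fold to 91.1 ± 4.09 FPKM (adjusted p = 3e-12) and Tpm2, a tropomyosin, 2.2-fold to 51.4 ± 13.4; Srf, Mrtfa and Flna also rose, while Mrtfb, Vcl and Csrp1 fell. Acta2, smooth muscle actin, was at 120.1 ± 11.1 FPKM in WT and 102 ± 32.3 in KO (adjusted p = 0.14), with 75.28 to 85.09 in KO replicates 1 to 4 and 141.13 and 145.52 in KO replicates 5 and 6. Adjusted over the list alone 8 were called, and the list did not pass (camera adjusted p = 0.71). Of 22 tested genes of modulated, synthetic smooth muscle cells, 8 rose and 10 fell, with 18 called adjusted over the list alone. Timp1 and S100a4 rose 5.12- and 1.86-fold, Tnfrsf11b, osteoprotegerin, fell 3.19-fold, and the list did not pass (camera adjusted p = 0.76).

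Most cell cycle genes did not pass the test between genotypes. Of 50 tested, 9 rose, Top2a, Ccnb2 and Ccnd1 fell, and 38 did not pass, with 10 called adjusted over the list alone (camera adjusted p = 0.71). Ccnd1, cyclin D1, fell 1.54-fold to 80 ± 7.92 FPKM, while Ccne1, cyclin E1, rose 3.38-fold to 8.54 ± 2.59 and Rrm1, a ribonucleotide reductase subunit, 1.92-fold to 24.6 ± 4.65. Mki67, a marker of cycling cells, was at 20.13 to 27.48 FPKM in the WT libraries, at 14.18 to 18 in KO replicates 1 to 4, and at 31.46 and 119.95 in KO replicates 5 and 6. With KO replicates 1 to 4 only, 30 of the 50 were lower and 9 higher in KO, and the list was lower (camera adjusted p = 0.024). Of 31 p53 target and senescence genes tested, 17 rose and 9 fell, with 26 called adjusted over the list alone (camera adjusted p = 0.076; 0.042 both without KO replicate 6 and with KO replicates 1 to 4 only). Mdm2, a target and inhibitor of p53, rose 2.54-fold to 71.9 ± 7.23 FPKM, Btg2 rose 2.08-fold, and Igfbp3 fell.

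**Figure D3:**
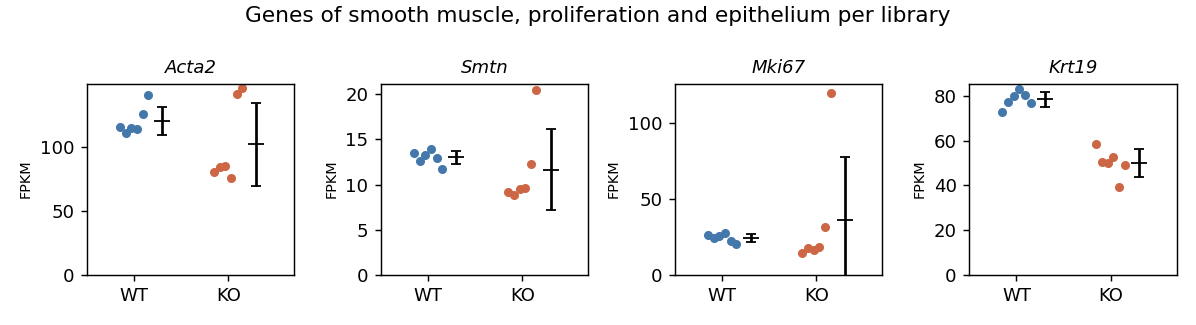
FPKM per library for Acta2, Smtn, Mki67 and Krt19, each point 1 library of WT (blue, 6) or KO (orange, 6), with the mean and SD as black bars; the SD bar of Mki67 reaches below 0 and is clipped there. KO replicates 5 and 6, the last points on the right, hold 31.46 and 119.95 FPKM of Mki67 and 141.13 and 145.52 of Acta2, above the other KO libraries.

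Most genes encoded by the mitochondrial genome were lower in KO. Of 13 tested, 11 fell and mt-Co2 and mt-Cytb did not pass, with 11 called adjusted over the list alone. mt-Nd4l fell 1.67-fold to 1037 ± 221 FPKM, mt-Nd4 1.55-fold to 1102 ± 188 and mt-Nd2 1.44-fold to 983 ± 77.1. The list was lower at a camera adjusted p of 0.017 (adjusted p = 0.67 with an estimated correlation), and the call was lost with quantile normalization (adjusted p = 0.54). The call of mt-Nd4 was lost there too, with its change going from -0.65 to -0.14 on the log2 scale (adjusted p = 0.14). As for mt-Co1 above, that scaling can take away differences in genes this abundant. Of 40 nuclear genes of the respiratory chain 20 rose and 9 fell, among them Cyc1, Cox7b and Ndufb8, which rose 1.81-, 1.58- and 1.5-fold. In that list 29 were called adjusted over the list alone; its camera adjusted p was 0.076 with all libraries, 0.017 without KO replicate 6 and 0.024 with KO replicates 1 to 4 only.

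Of 37 lysosome and autophagy genes, 17 rose and 7 fell, with 24 called adjusted over the list alone; Map1lc3a, which coats autophagosomes, rose 2.79-fold to 39.5 ± 6.17 FPKM, and the lysosomal enzyme gene Gla 2.3-fold. The camera adjusted p of that list was 0.2 with all libraries, 0.042 without KO replicate 6 and 0.0047 with KO replicates 1 to 4 only. Of 29 glycolysis and hypoxia genes tested, 13 rose and 7 fell, with 20 called adjusted over the list alone (camera adjusted p = 0.59). Slc16a3, the lactate exporter, rose from 0.255 ± 0.0554 to 9.48 ± 0.772 FPKM, and Pgam1 1.58-fold. Of 24 cholesterol synthesis genes tested, 9 rose and 11 fell, with 20 called adjusted over the list alone (camera adjusted p = 0.62). Mvd and Stard4 fell 1.5- and 1.68-fold.

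Chromatin enzymes, the subject named in the title of the series, changed in both directions. Of 59 tested chromatin and DNA methylation enzymes 16 rose, 21 fell and 22 did not pass, with 37 called adjusted over the list alone (camera adjusted p = 0.59). Kdm3a, a histone H3 lysine demethylase, fell 2.46-fold to 8.26 ± 0.855 FPKM and Tet3, which oxidises 5-methylcytosine, 2.35-fold to 2.84 ± 0.372. Nnmt, which consumes the methyl donor S-adenosylmethionine, rose 2.71-fold to 34.4 ± 5.81.

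Of 22 tested genes of angiotensin, endothelin and G protein signalling, 9 rose and 9 fell, with 18 called adjusted over the list alone (camera adjusted p = 0.76). The median change in this list was -0.03 on the log2 scale, while its mean of 0.30 and its test pointed up. Rgs4, a regulator of G protein signalling, rose from 0.455 ± 0.112 to 32.2 ± 17.4 FPKM, with 11.44 and 8.16 in KO replicates 5 and 6 and 42.16 to 44.62 in the others. Fosl2 rose 1.9-fold. Prkg1, the cyclic GMP-dependent kinase, was listed at 0 in the 6 WT libraries and at 1.11 to 1.54 FPKM in the KO libraries (adjusted p = 7.5e-10). Agtr1b, a receptor for angiotensin II, was listed at 0 in the WT libraries and at no more than 0.06 FPKM in KO. Agtr1a and Agtr2, the other receptor genes of the list, have no values under these symbols, so their RNA cannot be judged here.

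**Figure D4:**
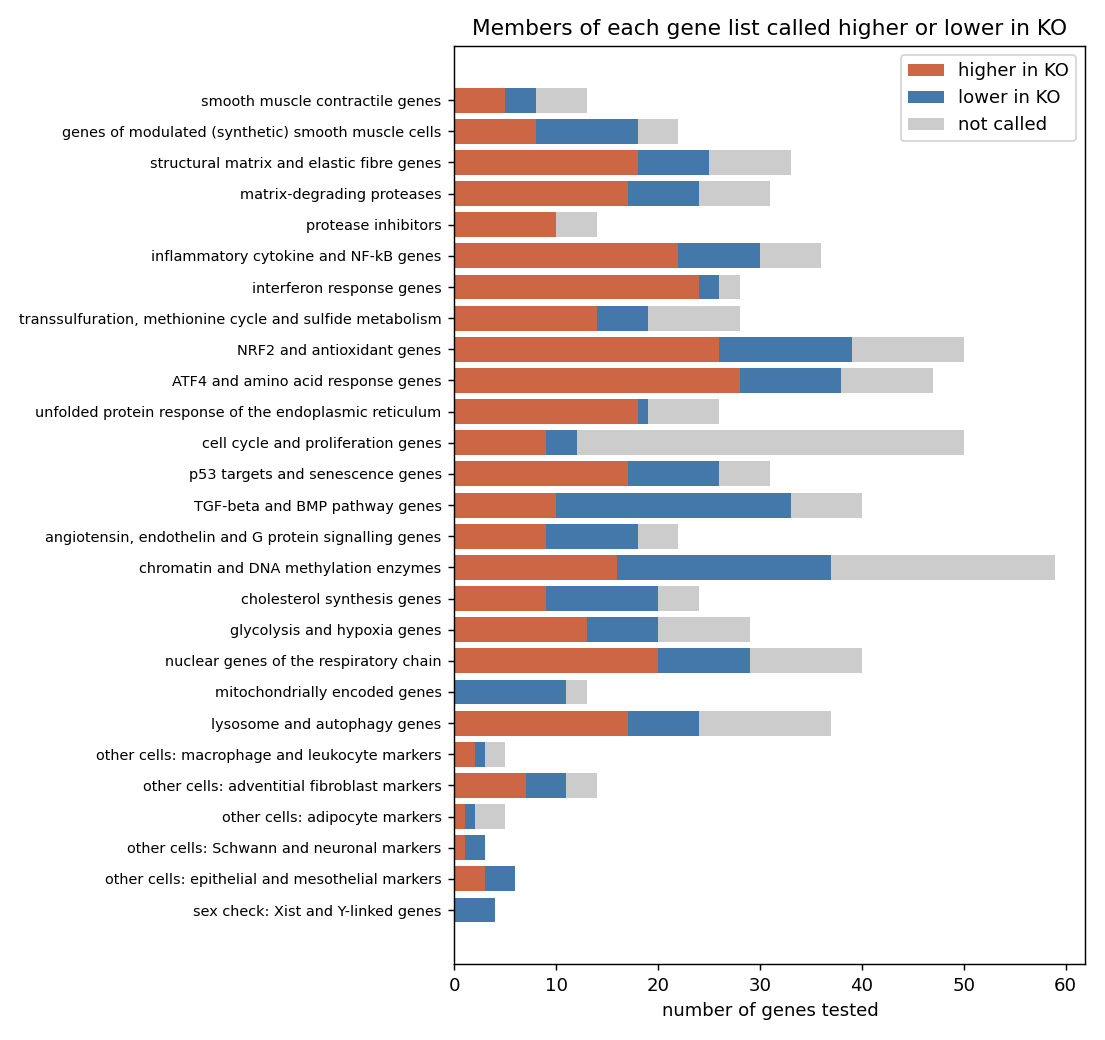
Number of tested genes in each of the 27 lists with at least 3 tested members, split into those called higher in KO (orange), lower in KO (blue) and not called (grey). Protease inhibitors hold 10 higher and 0 lower, interferon response genes 24 and 2, and TGF-beta and BMP pathway genes 10 and 23.

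Markers of other cell types did not move one way. Pecam1, Cdh5 and Ptprc were at most 0.22 FPKM in each library; of the endothelial markers Eng fell 2.15-fold from 48.3 ± 2.54 FPKM and Flt1 1.68-fold, the latter not called by an exact rank-sum test (adjusted p = 0.058). Among macrophage and leukocyte markers Cd68 rose from 1.62 ± 0.305 to 8.19 ± 2.62 FPKM and Csf1r from 0.707 ± 0.0924 to 3.05 ± 0.326, Cybb fell, and Cd14 and Cd74 did not pass. Of 14 adventitial fibroblast markers tested 7 rose and 4 fell: Dpt rose from 0.0433 ± 0.0677 to 15.5 ± 5.33 FPKM and Cd34 from 0.0167 ± 0.0186 to 1.3 ± 0.13, and Sfrp2 fell. Of the epithelial and mesothelial markers Cdh1, Krt19 and Msln fell, Krt19 from 78.5 ± 3.54 to 50.1 ± 6.25 FPKM, and Wt1, Upk3b and Upk1b rose, Wt1 to 1.51 ± 0.146. Acsl1 fell and Lipe rose among adipocyte markers, with a median change in that list of 0.14 and a mean and test pointing down (mean -0.09). Mbp and Pmp22 fell and Tubb3 rose among Schwann and neuronal markers, and Tnnt2 fell among cardiac and skeletal muscle markers. No red blood cell gene reached the threshold for testing. Adjusted over the list alone, 2 endothelial, 3 macrophage, 11 fibroblast, 6 epithelial, 2 adipocyte, 3 Schwann and 1 cardiac markers were called, as many as over all genes. None of the 5 of these lists with 3 or more tested members passed (camera adjusted p from 0.32 to 0.98).

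Genes that report the sex of the cells differed between the genotypes. Xist, transcribed from the inactive X chromosome of female cells, was at 0.01 to 0.04 FPKM in the WT libraries and at 2.31, 3.37, 3.16, 3.53, 0.31 and 0.63 in the KO libraries (exact permutation p = 0.00216, two-sided, the smallest that 924 assignments can give). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 12 libraries and fell in KO, Ddx3y from 11.1 ± 0.715 to 5.72 ± 1.2 FPKM, Eif2s3y from 11.7 ± 1.08 to 7.95 ± 1.36, Kdm5d from 2.94 ± 0.0668 to 1.21 ± 0.151 and Uty from 3.11 ± 0.3 to 1.35 ± 0.299. Xist did not reach the threshold for the main test; the 4 Y-linked genes were called adjusted over the list alone, and their list was lower in KO (camera adjusted p = 0.028; adjusted p = 0.67 with an estimated correlation). With TPM rescaling, which adds Xist to it, the list did not pass (adjusted p = 0.083). With genes of the autosomes only, 7190 of 11393 were called, 3595 in each direction. Xist and the Y-linked genes part the libraries just as genotype does, so this count cannot separate sex from genotype in autosomal genes.

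**Figure D5:**
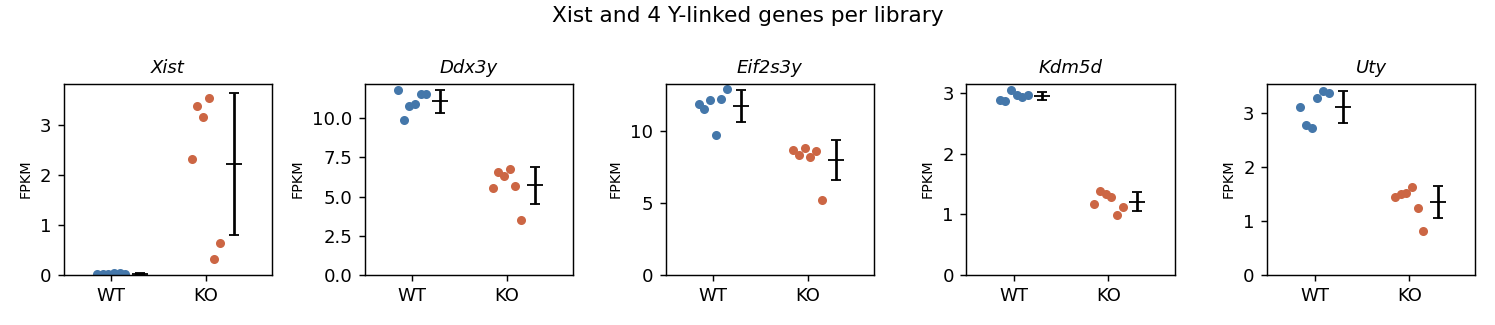
FPKM per library for Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, each point 1 library of WT (blue, 6) or KO (orange, 6), with the mean and SD as black bars. Xist is at most 0.04 FPKM in WT and 0.31 to 3.53 in KO, and each Y-linked gene is lower in the KO libraries than in the WT libraries but not absent.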

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

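Of the tests on these patterns, that of scaling was set before its result was seen; the others were chosen after. Single libraries standing far from the other 5 of their genotype were sought in 232 groups of 6 values, of which 23 met Dixon's criterion, where chance gives about 1 in 20.

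In WT, replicate 1 was the highest for Cth (0.08 FPKM, the others 0 to 0.02), Peg10 (0.01, the others at 0) and Csf3 (0.05, the others at 0). Replicate 5 was the highest for Cbs (0.44, the others 0.24 to 0.29), replicate 3 for Usp18 (0.41, the others 0.07 to 0.19), and replicate 6 for Bmp4 (71.7, the others 61.9 to 64.2) and Eng (53.4, the others 46.8 to 47.8). Replicate 2 was the lowest for Cald1 (27.4, the others 28.7 to 29.2).

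In KO, 9 of the 15 values were those of replicate 6. It was the lowest for Eif2s3y (5.21 FPKM, the others 8.15 to 8.77), mt-Co1 (4187, the others 5625 to 6415), Gpx8 (80.2, the others 96.9 to 106), Hsp90b1 (234, the others 243 to 248) and Slc16a3 (8, the others 9.31 to 10). It was the highest for Smtn (20.5, the others 8.81 to 12.3), Mki67 (120, the others 14.2 to 31.5) and Calr (263, the others 230 to 242), and its FPKM summed to 255538 where the other KO libraries summed to 275530 to 280348. Replicate 5 was the lowest for Lmod1 (0.46, the others 0.63 to 0.72) and Mark1 (25.1, the others 34.3 to 37.5) and the highest for S100a4 (639, the others 468 to 532), Atf4 (70.6, the others 63.4 to 65.6) and Rrm1 (34, the others 21.8 to 24.3). Replicate 1 was the highest for Tspan8 (1.11, the others 0.31 to 0.54).

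KO replicates 5 and 6 lay apart from the other KO libraries in Col3a1, Gpx3, Cxcl15, Mki67 and Acta2, among other genes. Scaling between the libraries is argued against: after quantile normalization the second principal component still held 14.2% of the variance, with these 2 libraries at its end. A smaller share of female cells, which their lower Xist could point to, would raise the Y-linked genes if male cells kept their level of them. The 4 Y-linked genes summed to 16.5 FPKM in replicate 5 and 10.6 in replicate 6, below the 16.8 to 17.9 of KO replicates 1 to 4. In replicate 5 the gap was small, and Ddx3y (5.69 FPKM) and Eif2s3y (8.6) lay within the range of KO replicates 1 to 4. Single Y-linked genes did not move alike, as given below, so the sum does not decide on this explanation. A separate culture, passage or day stays open and was not tested, since the labels name none. Beyond the share of female cells no biological explanation was tested, because the labels give these libraries the same genotype and treatment.

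Xist was present and Y-linked genes were lower in the KO libraries. Loss of the Y chromosome from male cells, with no female cells, is argued against by Xist, which was at least 0.31 FPKM in each KO library and at most 0.04 in WT. Mixing of female cells with male cells of unchanged Y-linked expression, in 1 share, would lower the 4 Y-linked genes alike, but the ratio of Eif2s3y to Kdm5d, taken as the most and the least retained of the 4, was at least 4.69 in KO and at most 4.35 in WT. With the choice of the pair repeated in each assignment of the libraries, the largest difference over the 6 pairs had an exact permutation p of 0.00216. A mixture of cells from both sexes together with a change of single Y-linked genes may remain, and was not tested.

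Protein coding genes at 1 FPKM or more in each KO library and at most 0.05 in each WT library numbered 73, and 2, Nkx2-1 and Epn3, showed the reverse. Depth is argued against, since the most frequent low value of short RNA genes differed by at most 1.12-fold between libraries. Within 10 Mb of Cth lay 0 of these genes, so a chromosome segment of that reach carried along with the targeted locus did not hold them. Only 24 tested genes lay there, fewer than the set, so it could not have held most of the set in any case. A longer segment was not tested. Cells of another type, added to unchanged WT-like cells that make up over 1 in 20 of the culture, are argued against by 11 genes. They are 11 of the 3952 protein coding genes at 10 FPKM or more in WT, and were over 20-fold lower in each KO library. Among them were Fscn1, Cdh1, Aqp1 and Sfrp2. A smaller share of WT-like cells, or added cells along with changed expression of these genes, cannot be excluded in this way. Cultures of different origin cannot be told apart from the genotype, which stays open as well, because the labels name no separate cultures or animals within a genotype; the highest correlation of a WT with a KO library was 0.895.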

How the results depend on the processing

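Of the alternative tests below, KO replicates 1 to 4 only, autosomal genes only and protein coding genes only were chosen after seeing the data; the adjustment for sex was not run, nor a count test. The 7515 calls were moved by over 1.5 times by 2 settings, through fewer genes or a further condition: a minimum of 5 FPKM left 4775 of 7244 genes (2505 higher, 2270 lower; 403 higher and 293 lower by a log2 of at least 1), and a log2 change of at least 1 left 1152 (738 higher, 414 lower). Genes lower by at least 1 numbered 681 with a pseudocount of 0.1 and 730 with 0.01, which shrink low genes less. TPM rescaling gave 1325 higher and 724 lower. It lets 14449 genes pass the filter and also raises all values against the pseudocount, and these 2 effects were not separated. The other settings gave 6854 to 10031 calls. Leaving out each library in turn gave 7121 to 8105 calls (3664 to 4252 higher, 3426 to 3853 lower), 734 to 755 higher and 380 to 442 lower by at least 1. Of 99 named genes, 95 kept direction and call under each setting run; Flt1, mt-Atp8, mt-Co1 and mt-Nd4 lost the call in 9 instances, 3 of them with quantile normalization, and none reversed.

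The 8 list calls became 0 with an estimated correlation, 3 with a minimum of 5 FPKM, 5 with protein coding genes and 13 with KO replicates 1 to 4 only; the cause was not tested beyond the first. In the last setting the cell cycle list reversed from higher, not called, to lower (adjusted p = 0.024). With no filter on low values 12 lists were called, the 4 added being proteases, NRF2 and antioxidant genes, p53 targets and the nuclear respiratory chain. Leaving out each library gave 7 to 12 list calls. Apart from the estimated correlation, 2 of the 8, protease inhibitors and the unfolded protein response, stayed called under each setting. Cth differed by -0.03 to -0.01 when each library was left out (lowest -0.0322 without WT replicate 2, exact permutation p = 0.0325; highest -0.01), and by -0.0388 with quantile normalization and no filter on low values (exact permutation p = 0.0411). Its size follows the scale: -0.208 with a pseudocount of 0.1, -0.959 with 0.01 and -0.0864 with TPM rescaling (exact permutation p = 0.143 each), and the authors' table lists it 5.39-fold higher in WT (p = 0.09, their test). Over its alternatives the exact permutation p ranged up to 0.275, without WT replicate 1. Limma with the replicate number as a block and no filter on low values gave an adjusted p of 0.309. The cause of this range was not tested. With the replicate number as a block 6959 genes and 8 lists were called; deviations of same-numbered libraries correlated at -0.27 to -0.058, so the numbers do not pair the libraries. Unknown depth limits statements on genes near 0 FPKM, Cth among them.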

Other observations

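The tests in this part were chosen after the values that prompted them were seen, except those over other splits of the libraries. Imprinted genes, expressed from 1 parental copy, differed in both directions. Peg10, Sgce and Grb10 were at most 0.05 FPKM in each WT library and at 1.96 ± 0.908, 4.04 ± 0.86 and 8.35 ± 1.17 FPKM in KO (n = 6). Igf2, the fetal growth factor, rose from 10.5 ± 0.736 to 55.1 ± 13.9 FPKM, while H19, the noncoding RNA beside it, fell from 5.09 ± 0.802 to 0.0717 ± 0.0564. Dlk1 fell from 24.2 ± 1.91 to 1.71 ± 0.107 FPKM, and its neighbours Meg3 and Rian from 2.78 ± 0.197 and 2.22 ± 0.0804 to 0.0167 ± 0.0121 and 0.01 ± 0.00894; Peg3 fell from 4.22 ± 0.488 to 0.0817 ± 0.0279. One hypothesis is that imprinted genes differ more often than other genes. Without Peg10, Sgce, Grb10, Meg3 and Rian, which prompted it, 4 of 13 tested members of a list of 34 imprinted genes were called with a log2 change of at least 1, 1 higher and 3 lower, against 1143 of 11813 other genes (Fisher's exact p = 0.0308, two-sided). Without Dlk1, a neighbour of Meg3 and Rian, it was 3 of 12 (Fisher's exact p = 0.103). Whether imprinted genes differ more often cannot be told from so few genes, and origin of the cultures stays open as above.

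Transcripts known from lung epithelium were present in the WT libraries. Nkx2-1, the transcription factor of lung and thyroid, was at 3.1 ± 0.366 FPKM in WT and 0.0117 ± 0.0183 in KO, Hopx at 2.73 ± 0.602 and 1.44 ± 0.757, and Abca3 at 12.8 ± 0.93 and 8.48 ± 1.87 (n = 6). Foxa2 was at 15.4 ± 0.676 and 13.5 ± 1.08 FPKM, and Lpcat1 was higher in KO, at 7.14 ± 0.375 against 4.87 ± 0.261. Without Nkx2-1, Cxcl15 and Cdh1, which prompted the hypothesis that WT cultures held lung epithelial cells, 4 of 19 measured genes in a list for lung epithelium were at 1 FPKM or more in each WT library and 3 in each KO library. Cells of that type with their abundant transcripts are argued against: Sftpb, Sftpc, Sftpd, Scgb1a1, Slc34a2 and Epcam were at most 0.11 FPKM in each WT library, over 20-fold below Nkx2-1. Epithelial cells that lost these transcripts in culture stay open and were not tested.

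KEGG pathway names of the deposited annotation gave 260 sets with 15 to 200 tested genes. Names with a quotation mark were kept apart, so valine, leucine and isoleucine degradation stands as 2 sets, and sets can be incomplete. Of the 260 sets, 1 passed the camera test: the ribosome, with 72 of 129 genes lower and 22 higher in KO (adjusted p = 0.0066, adjusted p = 1 with an estimated correlation). It stayed lower with each scaling run, with an adjusted p of 0.0099 with median-ratio, 0.0051 with TPM and 0.063 with quantile scaling, so the last ends the call. Many ribosomal protein genes share reads with processed pseudogenes, so their single values are uncertain.

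Nnt, a mitochondrial transhydrogenase gene, stands on 2 gene models. The first was listed at 0 in the 6 WT libraries and at 15.43, 2.69, 9.86, 14.35, 13.28 and 8.93 FPKM in the KO libraries; the second was at 10.13 to 11.44 FPKM in WT and 3.76 to 10.48 in KO. The models share their internal exons, so how reads were split between them is uncertain. The first model counts among the 73 protein coding genes above that were nearly absent from WT, although the second was present in each WT library. C57BL/6J mice, named for WT, are known to carry a deletion in Nnt. A difference in strain background between the genotypes stays open and was not tested.

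Whether other splits of the 12 libraries give as many calls was counted over 100 of the 462 splits into groups of 6. For genes, 1 of the 100 splits, the real one, called 7515, and the highest of the others called 2355. The first principal component already parted the genotypes and other splits mix them, so this count restates that parting. Libraries of a genotype may be technical repeats, so the count sets the difference against the spread between libraries only. It does not exclude chance differences between cultures. For gene lists, 33 of the 100 splits called at least as many as the real 8. The others called a median of 5 lists and at most 11, so chance is not excluded for the number of list calls.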
